A study of Homo sapiens with 4 samples.

How the data were processed

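RNA sequencing was carried out on SU-DHL-2 cells, 2 libraries given vehicle and 2 given Spautin-1 at 10 µM for 36 h. RNA was extracted with TRIzol and made into stranded mRNA libraries with a VAHTS kit, per the labels' protocols. Reads were trimmed with Trimmomatic 0.36 and assigned to genes of GRCh38 with featureCounts (Subread 1.5.1), and edgeR 3.12.1 was used, per the submitters' processing notes. The aligner, the annotation release, the strand setting of the counting and the handling of multi-mapped reads are not given in the sources used here. The values deposited by the authors are raw counts of reads per gene, with the coordinates, strand and exonic length of each gene per the file headers, for 61267 genes of which 31681 had at least 1 read. Of all genes, 33.3% are named by an Ensembl identifier alone. Totals per library are 34115420 and 38362526 counts for vehicle and 38325536 and 34893634 for Spautin-1; a gene with no count in a library was set to a floor of 3 counts where a bound was needed, which covers counting error only.

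Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group (minimum count 10, minimum total count 15), which left 18368, of which 12796 are protein-coding, and libraries were scaled by TMM, with factors of 1.02, 1.01, 0.980 and 0.994 for vehicle replicates 1 and 2 and Spautin-1 replicates 1 and 2. Spautin-1 was compared with vehicle by the edgeR quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values are TMM-scaled. The replicate numbers are not stated to mark a shared culture or day, so they entered the model only as an alternative. Biotypes and transcript GC content came from GENCODE 29, matched by gene symbol or identifier for 57053 genes, and GC content was available for 95.6% of the genes tested.

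The tests, 37 gene lists and the rule for named genes were fixed before the data were examined. The rule takes 9 genes tied to the compound, its targets and ferroptosis; the 8 largest increases and 8 largest decreases among called protein-coding genes with a mean of at least 5 CPM and no overlap between groups; and for each list the 2 called members with the smallest p in the main direction and the called member with the smallest p in the other direction. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 37 lists. Of the list entries, 1 was not in the count table.

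The alternatives fixed in advance were other scalings (RLE, upper quartile, library size), no filter or 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the edgeR exact test, robust empirical Bayes, a replicate block, loess offsets per library on GC content and on gene length (span 0.3), protein-coding genes alone, stricter thresholds, leaving out each library, and for the lists an estimated correlation, fry and cameraPR. Leaving out the mitochondrial genes, the offsets in the list tests and the GC offset combined with leaving out vehicle replicate 2 were added after the data were seen. GC content was compared with the changes over protein-coding genes with a mean of at least 4 CPM. The procedure was tested on simulated data of the same size in which 200 of 18368 genes were changed: edgeR recovered 19.4% of the 1.5-fold, 62.7% of the 2-fold and 87.9% of the 4-fold changes, and 7.38% of its calls were false. Reads were not analysed here.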

Results

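Gene expression was measured by RNA sequencing in SU-DHL-2, an established human cell line derived from a diffuse large B-cell lymphoma. Cells received either vehicle or Spautin-1, a small molecule described as an inhibitor of the deubiquitinating enzymes USP10 and USP13, at 10 µM for 36 h. Each group held 2 libraries, which leaves 2 residual degrees of freedom. The deposited raw counts summed to 34115420 and 38362526 in the vehicle libraries and to 38325536 and 34893634 in the Spautin-1 libraries. Between 25154 and 25683 genes had at least 1 read in each library. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these 4 samples, which may be technical.

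The series title names USP13, the small GTPase RAN and ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation. The comparison of the 2 groups gives the change in mRNA levels after exposure to the compound. Of 18368 genes tested, 2112 were higher and 1933 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), together 22.0% of the genes. In each of these 4045 genes both Spautin-1 libraries lay beyond both vehicle libraries, which follows largely from the call, made on the same libraries. Among all 18368 genes, the groups were separated in this way upward in 5664 and downward in 5619. Chance gives such a separation, either way, for 33.3% of genes. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333. At least a 2-fold change was seen for 764 of the higher and 559 of the lower genes. Among protein-coding genes with a mean of at least 5 CPM, the 8 largest increases included the signalling regulators RGS1 and RGS2, the orphan nuclear receptor NR4A2 and the NF-kB inhibitor TNFAIP3, while the interferon-induced genes MX1 and OAS3 were among the strongest decreases. Immediate early, NF-kB, cholesterol synthesis and endoplasmic reticulum stress genes were called higher as lists by camera, and DNA replication and ribosome biogenesis genes lower. None of these list calls held with an estimated correlation (camera adjusted p of 0.308 to 0.381). That setting tests on the 2 residual degrees of freedom, so it has little power here. Fewer genes passed when either Spautin-1 library was left out. Each time the lone remaining library was assumed to vary like the vehicle libraries, which differed from each other more than the Spautin-1 libraries did.

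The mRNAs of the proteins named in the series title and of the compound's stated targets did not pass the test. USP13 (chromosome 3, 179653032 to 179804366, GRCh38) was at 64.2 ± 10.7 CPM in vehicle and 66.8 ± 2.78 CPM in Spautin-1 (mean ± SD, n = 2 each), a log2 fold change of 0.06 ± 0.13 (± SE; edgeR adjusted p = 0.799). USP10 (chromosome 16, 84699986 to 84779922) gave a log2 fold change of -0.18 ± 0.12, adjusted p = 0.323, RAN (chromosome 12, 130872037 to 130877678), which drives transport through nuclear pores, 0.05 ± 0.09, adjusted p = 0.754, and BECN1 (chromosome 17, 42810134 to 42833350), a core autophagy protein, -0.05 ± 0.11, adjusted p = 0.775 (edgeR, Benjamini-Hochberg). Among the ferroptosis genes set in advance, ACSL4 (chromosome X, 109624244 to 109733403), which activates polyunsaturated fatty acids, rose 1.45-fold from 47.3 ± 8.16 to 68.6 ± 2.88 CPM (edgeR adjusted p = 0.0146). The glutathione peroxidase GPX4 (chromosome 19, 1103982 to 1106791) gave -0.15 ± 0.15, adjusted p = 0.51, the cystine transporter SLC7A11 (chromosome 4, 138164097 to 138242349) -0.38 ± 0.18, adjusted p = 0.168, the transferrin receptor TFRC (chromosome 3, 196012511 to 196082153) 0.33 ± 0.12, adjusted p = 0.0784 and the heme oxygenase HMOX1 (chromosome 22, 35380361 to 35394214) -0.42 ± 0.34, adjusted p = 0.419. UVRAG, a partner of BECN1, rose 1.82-fold from 24.9 ± 1.78 to 45.2 ± 1.66 CPM (edgeR adjusted p = 0.000714). In the preset list of compound targets and study genes, which does not hold HMOX1 or TFRC, ACSL4 and UVRAG were the 2 of 12 that passed, the same number when adjusted over the list alone. That list as a whole was not called (camera adjusted p = 0.811; its median log2 fold change was -0.07, or 0.03 without vehicle replicate 1, and its mean 0.06).

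Single libraries decided several of these values. Without vehicle replicate 2, SLC7A11 was called lower at -0.66 and USP10 at -0.30. A fit with 1 vehicle library takes its spread from the Spautin-1 libraries alone. It leaves out the difference between the vehicle libraries, which stood at 51.3 and 33.0 CPM for SLC7A11. SLC7A11 was also called by edgeR with the GC offset (-0.51, adjusted p = 0.0248) and with the replicate block (-0.35, adjusted p = 0.0482). Without vehicle replicate 1, GPX4 was called lower at -0.40 and TFRC higher at 0.50, under the same limit. TFRC was also called without a filter (0.32, adjusted p = 0.04) and with the replicate block (0.34, adjusted p = 0.0156). The vehicle library left out also moved values that did not pass. Without vehicle replicate 2, GPX4 was at 0.14 (adjusted p = 0.295), USP13 at -0.10 and TFRC at 0.17, and without vehicle replicate 1, USP13 was at 0.24 (adjusted p = 0.0792), SLC7A11 at -0.03 and USP10 at -0.05. HMOX1 ran from -0.78 without Spautin-1 replicate 1 and -0.68 without vehicle replicate 1 to -0.13 without Spautin-1 replicate 2 and -0.08 without vehicle replicate 2, and RAN from 0.02 to 0.08. GPX4 was at -0.06 and -0.26 without Spautin-1 replicate 1 and replicate 2. The call of ACSL4 was lost without Spautin-1 replicate 1 (log2 fold change 0.57, adjusted p = 0.0543) and without Spautin-1 replicate 2 (0.50, adjusted p = 0.125). USP13, BECN1 and SLC7A11 overlap other genes, so some of their reads may belong to these.

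**Figure D1:**
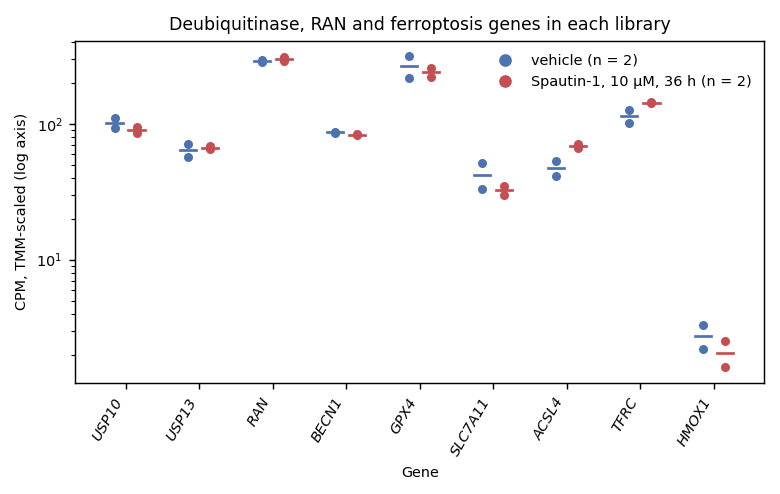
CPM (TMM-scaled, log axis) of the 9 genes fixed in advance in each library; points are libraries, lines are group means, blue is vehicle (n = 2) and red is Spautin-1 (n = 2). ACSL4 is the gene among them that passed the test, and the vehicle libraries of GPX4 stand at 217 and 315 CPM.

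Among called protein-coding genes with a mean of at least 5 CPM, the largest increase was in RGS1 (chromosome 1, 192575763 to 192580024), a GTPase-activating protein that dampens G-protein signalling, which rose 78.8-fold from 3.0 ± 0.00553 to 236 ± 10.2 CPM (mean ± SD, n = 2 each; edgeR adjusted p = 1.01e-10). RGS2 (chromosome 1, 192809039 to 192812275), of the same family, rose 10.6-fold from 3.9 ± 0.631 to 41.3 ± 2.75 CPM. NR4A2 (chromosome 2, 156324437 to 156342348), a stimulus-induced nuclear receptor, rose 57.2-fold from 0.478 ± 0.383 CPM, a level resting on 26 and 8 reads; its log2 fold change of 5.84 became 6.99 without vehicle replicate 1 and 5.16 without vehicle replicate 2. IL23A (chromosome 12, 56334174 to 56340410), a subunit of interleukin-23, rose 10.6-fold, and TNFAIP3 (chromosome 6, 137867214 to 137883314), the A20 protein that restrains NF-kB, rose 7.44-fold from 22.1 ± 0.26 to 165 ± 0.314 CPM. The deubiquitinase OTUD1 (chromosome 10, 23439075 to 23442377) rose 8.81-fold, the inducible chaperone HSPA6 (chromosome 1, 161524540 to 161526894) 8.18-fold and the acetyl-CoA synthetase ACSS2 (chromosome 20, 34872146 to 34927962) 8.05-fold. These 8 genes had edgeR adjusted p-values between 1.01e-10 and 1.16e-05.

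Under the same limits the strongest decreases were smaller. PROB1 (chromosome 5, 139390592 to 139395104) fell 3.88-fold, and MX1 (chromosome 21, 41420020 to 41470071), an interferon-induced antiviral GTPase, fell 3.69-fold from 50.3 ± 2.13 to 13.7 ± 0.494 CPM (edgeR adjusted p = 3.4e-06). TMIE (chromosome 3, 46694528 to 46710886), known from hair-cell mechanotransduction, fell 3.52-fold. OAS3 (chromosome 12, 112938051 to 112976460), which makes the second messenger of the antiviral RNase L pathway, fell 3.29-fold, the metalloreductase-family protein STEAP1 (chromosome 7, 90154456 to 90164829) 3.19-fold and CHMP6 (chromosome 17, 80991598 to 81009517), a subunit of the ESCRT-III membrane-remodelling complex, 3.15-fold. GCHFR (chromosome 15, 40764068 to 40767708), the feedback regulator of GTP cyclohydrolase, fell 2.93-fold, and the zinc-finger gene ZNF587B (chromosome 19, 57819721 to 57846238) fell 2.88-fold. Their adjusted p-values in the edgeR test ran from 3.4e-06 to 0.000851. ZNF587B shares exonic bases with another gene on the same strand, and GCHFR, MX1 and TNFAIP3 overlap genes on the opposite strand, so reads may be split between them; whether the counting used the strand of the reads is not given in the sources used here.

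**Figure D2:**
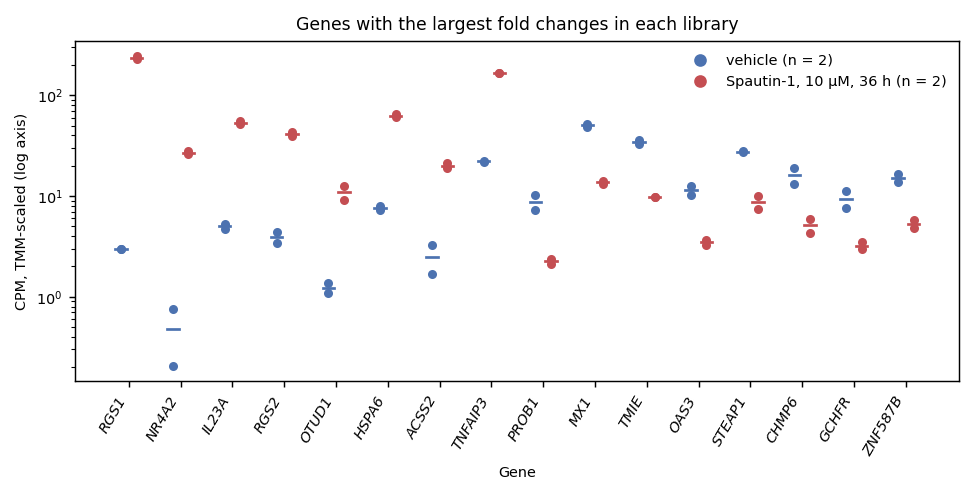
CPM (TMM-scaled, log axis) in each library of the 8 genes with the largest increase and the 8 with the largest decrease among called protein-coding genes with a mean of at least 5 CPM and no overlap between the groups; points are libraries, lines group means, blue vehicle (n = 2), red Spautin-1 (n = 2). RGS1 goes from 3.0 to 236 CPM and MX1 from 50.3 to 13.7 CPM, with both Spautin-1 libraries beyond both vehicle libraries in all 16 genes.

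Ferroptosis genes moved in both directions. Among genes listed in advance as suppressors of ferroptosis, 4 of 26 tested genes rose and 2 fell over all genes tested, the same numbers when adjusted over the list alone. Of all genes tested, 22.0% were called, so some called members alone are no sign of a change in this or any other list. The sterol enzyme SC5D rose 1.69-fold, GCH1, which starts tetrahydrobiopterin synthesis, 1.81-fold, the glutathione synthetase GSS 1.38-fold, ACSL3, which activates monounsaturated fatty acids, rose 1.54-fold, while CHMP6 and thioredoxin reductase TXNRD1 fell, the latter 2.23-fold from 403 ± 48.9 to 181 ± 2.14 CPM (edgeR adjusted p = 2.38e-05). Among genes listed in advance as drivers, 9 of 25 rose and 2 fell (10 and 7 adjusted over the list alone). The polyamine-catabolic enzyme SAT1 rose 4.2-fold from 156 ± 0.786 to 657 ± 8.8 CPM, and the stress transcription factor ATF3 rose 3.5-fold. CHAC1, which degrades glutathione, fell 2.24-fold from 6.94 ± 0.368 CPM, and the lipoxygenase ALOX12 fell 2.94-fold. Neither list was called as a whole (suppressors, camera adjusted p = 0.663, with a median of 0.07 and a mean of -0.01; drivers, camera adjusted p = 0.634, with a median of -0.01 and a mean of 0.02), although cameraPR on the edgeR statistics (adjusted p = 0.00685) and fry (adjusted p = 0.0482) called the drivers. The median of the drivers turned positive whichever library was left out, with the highest value, 0.15, without vehicle replicate 2, and was 0.09 with the GC offset. In fits without vehicle replicate 1, vehicle replicate 2, Spautin-1 replicate 1 and Spautin-1 replicate 2, in that order, 10, 9, 4 and 4 drivers were called higher and 3, 5, 1 and 2 lower, and for the suppressors 5, 6, 2 and 3 were higher and 4, 4, 2 and 2 lower. ACSL3 was no longer called without Spautin-1 replicate 1 (adjusted p = 0.051).

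In the list of targets of NRF2, the transcription factor of the antioxidant response, 7 of 23 tested genes were lower and none was higher, 7 and 0 adjusted over the list alone. For the NRF2 list, camera gave adjusted p = 0.0426, and adjusted p = 0.375 with an estimated correlation. NQO1, a quinone reductase, fell 2.32-fold from 18.5 ± 1.54 to 7.95 ± 0.0621 CPM (edgeR adjusted p = 0.000359), and TXNRD1 belongs to this list as well. The list's call was narrow: it was lost without vehicle replicate 1 (adjusted p = 0.117), Spautin-1 replicate 1 (0.0794) or Spautin-1 replicate 2 (0.0519), with an offset for GC content (0.0501) and with a replicate block (0.0702), and 3 and 4 members were lower without Spautin-1 replicate 1 and replicate 2. Without vehicle replicate 1 and without vehicle replicate 2, 1 member was called higher. Iron-handling genes showed no common direction: 3 of 25 rose, the metal transporter SLC11A2 (log2 fold change 0.60 ± 0.19), the cysteine desulfurase NFS1 (0.60 ± 0.20) and the iron chaperone PCBP2 (0.35 ± 0.10), and FECH, the last enzyme of heme synthesis, fell 1.78-fold. Adjusted over the list alone, 0 were higher and 1 lower (camera adjusted p = 0.811). When vehicle replicate 1, vehicle replicate 2, Spautin-1 replicate 1 or Spautin-1 replicate 2 was left out, in that order, 5, 3, 0 and 0 iron-handling genes were higher and 5, 3, 1 and 0 lower. SLC11A2 and PCBP2 were no longer called without Spautin-1 replicate 1 or replicate 2, nor SLC11A2 without vehicle replicate 2 or FECH without Spautin-1 replicate 2 (adjusted p between 0.0557 and 0.257). SLC11A2 also missed the threshold with DESeq2 (0.079) and library size scaling (0.0563), and SLC11A2 and PCBP2 with the length offset (0.0539 and 0.0511).

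Of 23 tested genes of cholesterol synthesis, 14 were higher and none lower (15 and 1 adjusted over the list alone), with a median log2 fold change of 0.64. For cholesterol synthesis, camera gave adjusted p = 0.000182, and adjusted p = 0.308 with an estimated correlation. HSD17B7, which acts late in the pathway, rose 2.84-fold from 8.64 ± 0.612 to 24.5 ± 1.54 CPM, and ACAT2, which makes acetoacetyl-CoA, rose 3.52-fold from 60.9 ± 2.27 to 214 ± 9.32 CPM (edgeR adjusted p = 8.9e-07). ACAT2 overlaps SOD2 and TCP1 on the opposite strand, and 2 list members were called lower without vehicle replicate 1 and 1 without vehicle replicate 2. In fatty acid synthesis and desaturation, 6 of 16 genes rose and 1 fell, the same adjusted over the list alone, without a call for the list (camera adjusted p = 0.241): ACSS2 and ACSL3 rose, and SREBF1, the transcription factor of lipogenesis, fell 1.66-fold. Without Spautin-1 replicate 1 and replicate 2, 1 and 2 genes of that list were higher, and without vehicle replicate 1, 2 were lower. SREBF1 was not called without Spautin-1 replicate 2 (adjusted p = 0.142).

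PPP1R15A, the phosphatase subunit that reverses eIF2 alpha phosphorylation, rose 7.32-fold from 289.5 ± 5.82 to 2118 ± 51.4 CPM (edgeR adjusted p = 2e-09), and DDIT3, the pro-apoptotic factor CHOP, rose 5.87-fold from 20.4 ± 1.69 to 119.6 ± 8.47 CPM. In the list of ATF4 and integrated stress response genes, 8 of 28 rose and 2, CHAC1 and the phosphoserine phosphatase PSPH (1.52-fold), fell (8 and 3 adjusted over the list alone). The list missed the threshold (camera adjusted p = 0.0718) and passed it with the GC offset (0.042), by fry (0.0419) and by cameraPR (3.96e-07). Of 25 genes of the unfolded protein response, 9 rose and none fell (11 and 0 adjusted over the list alone). For the unfolded protein response, camera gave adjusted p = 0.00104, and adjusted p = 0.308 with an estimated correlation. HERPUD1, part of the degradation machinery of the endoplasmic reticulum, rose 5.52-fold from 59.2 ± 4.61 to 327 ± 19.6 CPM, and the stress sensor ERN1 (IRE1) rose 4.28-fold. Without vehicle replicate 1 and without vehicle replicate 2, 14 members were higher, and without Spautin-1 replicate 2, 6, while 3 were lower without vehicle replicate 1. In the ATF4 list 4, 6, 1 and 1 members were lower without vehicle replicate 1, vehicle replicate 2, Spautin-1 replicate 1 and Spautin-1 replicate 2. DDIT3 overlaps other genes on both strands.

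In the list of heat shock and chaperone genes, which does not hold HSPA6, 8 of 18 fell and 2 rose (9 and 2 adjusted over the list alone). DNAJA1, an HSP70 co-chaperone, fell 2.09-fold from 1425 ± 1.48 to 681 ± 16.1 CPM (edgeR adjusted p = 6.12e-06), the inducible HSP90AA1 fell 1.36-fold, and HSP90AB1, the constitutive form, and the co-chaperone BAG3 rose 1.27-fold and 1.36-fold. Without vehicle replicate 2, 4 members were higher, and without either Spautin-1 library 1. The list was not called (camera adjusted p = 0.0743), but passed without vehicle replicate 1 (0.0464), with a filter of 1 CPM in 2 libraries (0.0477) and by cameraPR (0.000867). Of 32 proteasome genes, 3 fell and none rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.406), with PSMD12 at -0.65 ± 0.12, PSMA7 at -0.52 ± 0.17 and PSMC3 at -0.43 ± 0.10 on the log2 scale. Among the 44 tested deubiquitinases of the list, which does not hold OTUD1, 6 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.415; the median and mean were -0.10 and -0.03, while fry, at adjusted p = 0.825, pointed upward). TNFAIP3 and USP12 (1.92-fold) rose, UCHL3 and OTUD6B fell 1.35-fold and 1.47-fold, and USP7, which stabilises MDM2, fell 1.92-fold from 306 ± 34.8 to 159 ± 1.56 CPM (edgeR adjusted p = 0.00011). In fits without vehicle replicate 1, vehicle replicate 2, Spautin-1 replicate 1 and Spautin-1 replicate 2, in that order, 7, 2, 3 and 1 proteasome genes were lower and 1, 1, 0 and 0 higher, and 6, 8, 2 and 3 deubiquitinases were higher and 9, 8, 2 and 1 lower. PSMC3 was not called without Spautin-1 replicate 2 (adjusted p = 0.193).

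Autophagy genes changed in both directions, 7 of 37 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.234, fry 0.0239). The cargo receptor NBR1 rose 2.12-fold from 43 ± 0.0577 to 91.4 ± 1.5 CPM (edgeR adjusted p = 5.6e-05) and the lipid-transfer protein ATG2A fell 1.69-fold, as did ATG101 (1.44-fold), ATG7 (1.63-fold) and the receptor SQSTM1 (1.36-fold). Of 35 lysosomal genes, 4 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.894). Among them, the protease CTSH rose 1.49-fold, the enzyme SGSH 1.92-fold, the cholesterol exporter NPC1 1.58-fold, and CLN3 fell 1.46-fold. When vehicle replicate 1, vehicle replicate 2, Spautin-1 replicate 1 or Spautin-1 replicate 2 was left out, in that order, 11, 8, 4 and 4 autophagy genes were higher and 5, 3, 1 and 0 lower, and 4, 3, 1 and 1 lysosomal genes were higher and 5, 2, 0 and 0 lower. The calls of NPC1 and CLN3 were lost without Spautin-1 replicate 1 or replicate 2, and that of ATG2A without Spautin-1 replicate 2 (adjusted p between 0.0518 and 0.191).

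Lists of proliferation genes were lower. Of 41 genes of the G1/S transition and DNA replication, 25 were lower and 1 was higher (28 and 1 adjusted over the list alone), with a median log2 fold change of -0.45. For the replication list, camera gave adjusted p = 2.23e-07, and adjusted p = 0.308 with an estimated correlation. UHRF1, which maintains DNA methylation at replication forks, fell 2.58-fold from 339 ± 17.9 to 131 ± 9.47 CPM (edgeR adjusted p = 5.8e-06), and the flap endonuclease FEN1 fell 1.75-fold. The exception, the cyclin CCND2, rose 1.99-fold at 1.25 ± 0.06 CPM in vehicle, with an adjusted p of 0.0483. That call was lost when any of the 4 libraries was left out (0.0554 to 0.183) and in 10 other settings (0.051 to 0.122), among them DESeq2, limma-voom and the GC offset. Of 39 genes of G2/M and mitosis, 11 fell and none rose (12 and 0 adjusted over the list alone); the mitotic kinase PLK1 fell 2.16-fold and the spindle motor KIF11 1.63-fold. For the mitotic list, camera gave adjusted p = 0.0149, and adjusted p = 0.429 with an estimated correlation. Of 47 genes of the RAN cycle and nuclear transport, 11 fell and none rose, the same adjusted over the list alone: the nuclear pore protein NUP153 fell 1.79-fold and the GTPase activator RANGAP1 1.52-fold, while RAN itself was at 0.05. For the transport list, camera gave adjusted p = 0.0257, and adjusted p = 0.429 with an estimated correlation. In fits without vehicle replicate 1, vehicle replicate 2, Spautin-1 replicate 1 and Spautin-1 replicate 2, in that order, 30, 26, 15 and 12 of the replication genes, 14, 17, 6 and 2 of the mitotic genes and 14, 17, 5 and 4 of the transport genes were lower. Without vehicle replicate 1, 3 mitotic and 3 transport genes were higher. The call of the transport list was lost without vehicle replicate 1 (adjusted p = 0.105), Spautin-1 replicate 1 (0.0794) or Spautin-1 replicate 2 (0.0905), and that of the mitotic list without Spautin-1 replicate 1 (0.0504) or replicate 2 (0.0956).

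Ribosome biogenesis and ribosomal protein genes moved apart. In the list of MYC and ribosome biogenesis genes, 15 of 34 fell and 2 rose (18 and 2 adjusted over the list alone). For the biogenesis list, camera gave adjusted p = 0.00109, and adjusted p = 0.381 with an estimated correlation. The ribosome assembly factors GRWD1 and NOP16 fell 2.08-fold and 1.73-fold, MYC itself rose 1.61-fold from 78.8 ± 13.2 to 127 ± 3.15 CPM (edgeR adjusted p = 0.00255), and the nucleolar protein NPM1 rose 1.25-fold. Of 53 mRNAs of cytosolic ribosomal proteins, 33 rose and none fell (37 and 1 adjusted over the list alone), at a median of 0.42 on the log2 scale; RPL12 rose 1.7-fold and RPLP0 1.68-fold. For ribosomal proteins, camera gave adjusted p = 1.54e-07, and adjusted p = 0.539 with an estimated correlation. Ribosomal protein genes have many near-identical pseudogenes, so their counts are uncertain, and fry did not call the list (adjusted p = 0.0701). Without Spautin-1 replicate 2, 6 biogenesis genes were lower and 15 ribosomal protein mRNAs higher, and without vehicle replicate 1 and Spautin-1 replicate 1, 2 and 1 ribosomal protein mRNAs were lower. Replication-dependent histone mRNAs, which lack a poly(A) tail, had a median of -0.67 over 14 tested genes, of which 2 fell and none rose, the same adjusted over the list alone: H2AC6 fell 1.72-fold and H2AC13 4.13-fold, the latter from 0.927 CPM. For histone mRNAs, camera gave adjusted p = 0.0149, and adjusted p = 0.336 with an estimated correlation. The histone call was lost without vehicle replicate 2 (adjusted p = 0.0808, median -0.42), with a filter of 1 CPM in 2 libraries (0.0775) and by cameraPR (0.108). H2AC13 was not called whichever library was left out (0.0989 to 0.125), nor with DESeq2 (0.073) or with the block and the GC offset together (0.0518). H2AC6 was not called without Spautin-1 replicate 2 (0.0702).

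Of 24 p53 targets, 10 were higher and none lower (12 and 0 adjusted over the list alone), with the growth arrest gene GADD45A up 4.31-fold and the exonuclease AEN up 2.04-fold from 91.5 ± 3.94 to 187 ± 1.59 CPM. For p53 targets, camera gave adjusted p = 0.000182, and adjusted p = 0.308 with an estimated correlation. Of 19 apoptosis regulators, a list of both inhibitors and promoters of cell death, 9 rose and none fell (11 and 0 adjusted over the list alone). For the apoptosis regulators, camera gave adjusted p = 9.78e-05, and adjusted p = 0.308 with an estimated correlation. The 2 with the smallest p, the inhibitors of apoptosis BIRC3 and BCL2L1, were up 3.21-fold from 80.6 ± 2.87 to 258 ± 10.7 CPM and 2.29-fold from 21.4 ± 1.69 to 48.9 ± 1.46 CPM (edgeR adjusted p = 1.17e-06 and 7.78e-05). Without Spautin-1 replicate 1, 6 p53 targets were higher; without vehicle replicate 1, 1 p53 target and 2 apoptosis regulators were lower, and without vehicle replicate 2, 1 p53 target.

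Of 29 NF-kB targets, 14 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.55. For NF-kB targets, camera gave adjusted p = 3.75e-05, and adjusted p = 0.308 with an estimated correlation. After TNFAIP3, the chemokine receptor CCR7 rose 6.36-fold from 4.91 ± 0.0612 to 31.2 ± 2.76 CPM (edgeR adjusted p = 1.07e-06), and the activation marker CD83 and TNFAIP2 fell 1.49-fold and 1.5-fold; without either Spautin-1 library, 1 member was lower. Of 11 JAK-STAT3 targets, 6 rose and none fell, the same adjusted over the list alone: the interleukin-2 receptor chain IL2RA rose 4.14-fold and the feedback inhibitor SOCS3 3.76-fold. For JAK-STAT3 targets, camera gave adjusted p = 0.00154, and adjusted p = 0.308 with an estimated correlation. Of 21 immediate early genes, 14 rose and 1 fell (14 and 3 adjusted over the list alone), led by NR4A2 and NR4A3, the latter up 13-fold from 0.495 ± 0.114 CPM. For the immediate early genes, camera gave adjusted p = 0.000182, and adjusted p = 0.329 with an estimated correlation. The median of this list was 1.07, and 0.65 without vehicle replicate 1, where 3 members were lower. IER2, the member that fell, at -0.59 ± 0.18, was not called without vehicle replicate 2, Spautin-1 replicate 1 or Spautin-1 replicate 2 (adjusted p = 0.078, 0.0663 and 0.258). In the list of metallothioneins, which bind zinc and copper, 5 of 6 tested genes rose and none fell, the same adjusted over the list alone; the sixth, the zinc transporter SLC30A1, was not called. For the metallothioneins, camera gave adjusted p = 0.000901, and adjusted p = 0.308 with an estimated correlation. MT1X rose 7.85-fold from 0.421 ± 0.0261 CPM, MT1F 6.09-fold, MT1G 3.16-fold and MT2A 1.6-fold, and MT1E had 0 reads in both vehicle libraries and 26 and 22 in the Spautin-1 libraries, at least 8.1-fold higher against a floor of 3 counts per library. The levels of the metallothioneins are low, the genes resemble each other closely, and 3 were called without vehicle replicate 1 and without Spautin-1 replicate 2.

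**Figure D3:**
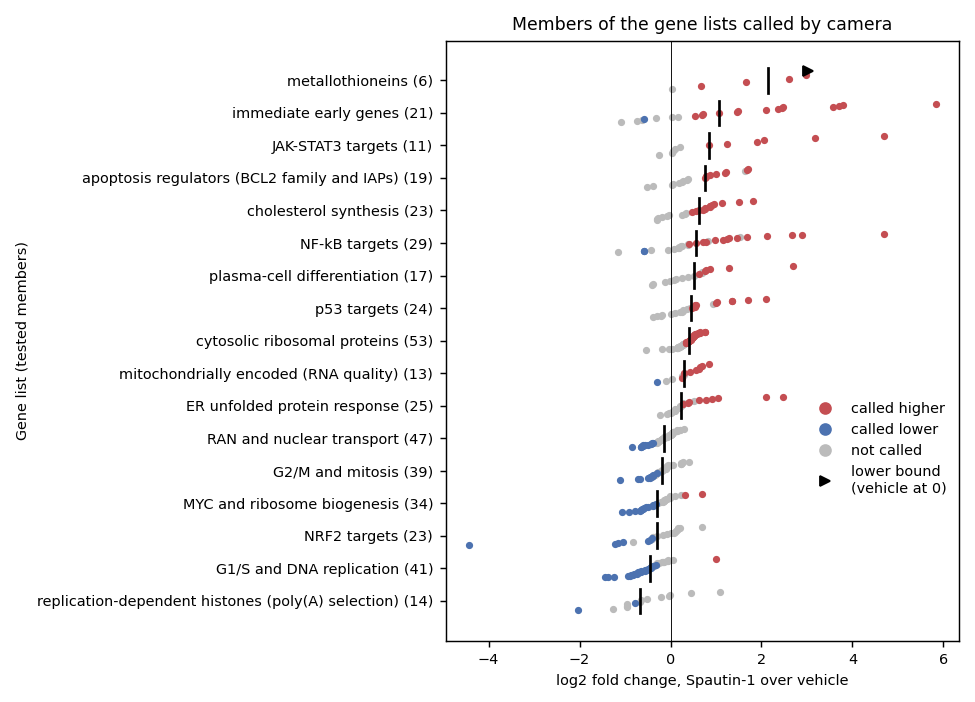
Log2 fold change, Spautin-1 over vehicle (x axis), of each tested member of the 17 gene lists called by camera (y axis, with the number of tested members); red points were called higher, blue lower and grey not called, bars are list medians, and the triangle is the lower bound for MT1E. Immediate early genes have a median of 1.07 and G1/S and DNA replication genes of -0.45.

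Genes of B-cell identity and immune function changed in different directions. Of 33 genes of B-cell receptor signalling and identity, 14 rose and 4 fell (14 and 5 adjusted over the list alone): FOXP1, a transcription factor of B-cell lymphoma, rose 2.94-fold, the co-activator POU2AF1 rose 2.5-fold and the germinal-centre repressor BCL6 fell 1.7-fold from 47.2 ± 1.38 to 27.8 ± 0.367 CPM (edgeR adjusted p = 0.00116). SPIB, POU2F2 and SYK fell 1.54-fold, 1.51-fold and 1.35-fold, and without either Spautin-1 library 2 members were lower. The list was not called (camera adjusted p = 0.0651), but passed with the GC offset (0.0326), by fry (0.00516) and by cameraPR (0.00504). Of 17 plasma-cell differentiation genes, 6 rose and none fell (7 and 1 adjusted over the list alone). For the plasma-cell genes, camera gave adjusted p = 0.0149, and adjusted p = 0.336 with an estimated correlation. PRDM1, the repressor that drives plasma-cell differentiation, rose 6.44-fold from 18.7 ± 0.421 to 121 ± 9.51 CPM (edgeR adjusted p = 9.81e-08), and IRF4 rose 2.43-fold; without vehicle replicate 1, 1 member was lower. Interferon response genes divided, with 10 of 32 lower and 6 higher (12 and 6 adjusted over the list alone; camera adjusted p = 0.0718, fry 0.00541, cameraPR 0.0314): MX1 and OAS3 fell and the guanylate-binding protein GBP2 rose 3.04-fold from 2.34 ± 0.132 CPM. In antigen presentation, 7 of 20 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.102, fry 0.0489): the class II genes HLA-DMB and HLA-DRA rose 2.83-fold and 2.88-fold at vehicle levels of 2.12 and 1.64 CPM, and the class I genes HLA-C and HLA-B fell 1.65-fold and 1.53-fold. HLA-C was not called with DESeq2 (adjusted p = 0.14), and its log2 fold change of -0.72 was -0.32 without vehicle replicate 2 (adjusted p = 0.0028). Without Spautin-1 replicate 1 and replicate 2, 3 and 3 interferon genes were higher and 7 and 6 lower, and 3 and 3 antigen presentation genes were higher and 1 and 2 lower, against 4 lower without vehicle replicate 1. HLA genes are highly variable in sequence and resemble each other, so their counts are uncertain.

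The mitochondrially encoded share of all counts was 5.25 and 4.94% in the vehicle libraries and 8.34 and 7.63% in the Spautin-1 libraries. The rRNA MT-RNR2 alone went from 1.35 and 1.28% to 3.29 and 3.05%. The mitochondrial mRNAs together went from 3.78 and 3.54% to 4.93 and 4.46%. Of the 13 mitochondrial mRNAs, 8 rose and 1 fell (10 and 1 adjusted over the list alone). For the mitochondrial mRNAs, camera gave adjusted p = 0.0149, and adjusted p = 0.601 with an estimated correlation. MT-CO1, a cytochrome oxidase subunit, rose 1.79-fold from 4109 ± 329 to 7365 ± 246 CPM (edgeR adjusted p = 1.77e-05), MT-CYB rose 1.55-fold, and MT-ND1 fell 1.22-fold (adjusted p = 0.0479). The list was not called without Spautin-1 replicate 1 (adjusted p = 0.12) or by fry (0.0907). MT-ND1, at -0.29, was at -0.45 without Spautin-1 replicate 1 (0.00966) and was not called without Spautin-1 replicate 2 (-0.15, adjusted p = 0.542), with DESeq2 (0.0725), with the exact test (0.0911) or with the length offset (0.134). Of the nuclear-encoded subunits of oxidative phosphorylation, 5 of 53 rose and 1 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.50), among them UQCRB at a log2 fold change of 0.60 ± 0.09, NDUFS4 at 0.47 ± 0.12, COX6C at 0.42 ± 0.09, COX7C at 0.35 ± 0.10 and NDUFS7 at -0.55 ± 0.18. In glycolysis and hypoxia, 8 of 33 rose and 4 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.127, fry 0.0419): the aldolase ALDOC rose 2.36-fold, NDRG1 2.2-fold, and lactate dehydrogenase LDHA, the phosphofructokinase PFKP, the glucose transporter SLC2A1 and the lactate transporter SLC16A3 fell 1.37-fold, 1.38-fold, 1.98-fold and 1.92-fold. When vehicle replicate 1, vehicle replicate 2, Spautin-1 replicate 1 or Spautin-1 replicate 2 was left out, in that order, 6, 10, 2 and 1 oxidative phosphorylation genes were higher and 10, 3, 0 and 0 lower, and 9, 8, 5 and 3 glycolysis genes were higher and 4, 4, 2 and 2 lower. NDUFS7 was not called without vehicle replicate 2, where it stood at -0.26, Spautin-1 replicate 1 or Spautin-1 replicate 2 (adjusted p = 0.17, 0.249 and 0.0654), nor COX6C or LDHA without Spautin-1 replicate 2 (0.0785 and 0.0607).

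**Figure D4:**
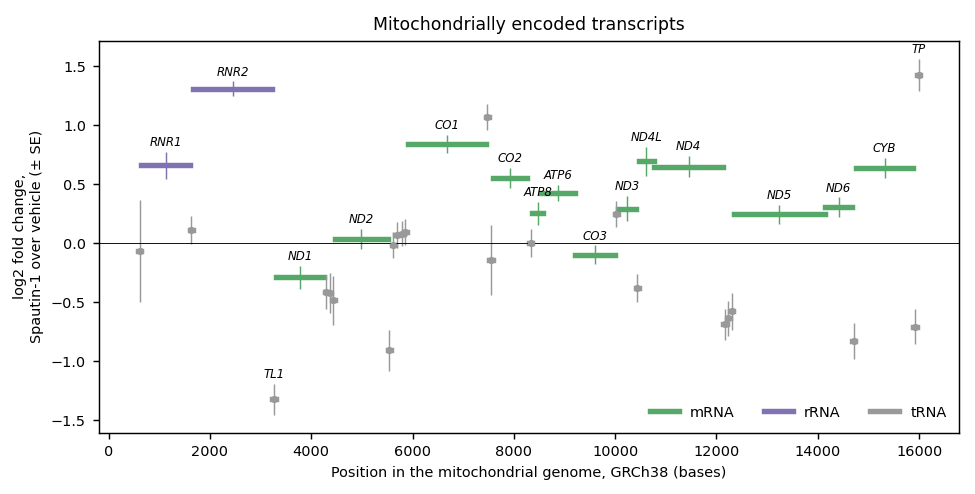
Log2 fold change, Spautin-1 over vehicle (y axis, ± SE), of the mitochondrially encoded genes at their position in the mitochondrial genome (x axis, bases, GRCh38); bars span each gene, with mRNAs in green, rRNAs in purple and tRNAs in grey. MT-RNR2 stands at 1.31 and MT-ND1, the next mRNA along the genome, at -0.29.

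Of 6 tested targets of the aryl hydrocarbon receptor, TIPARP rose 2.26-fold and NQO1 fell, the same adjusted over the list alone. The list had a median of -0.65 and was not called (camera adjusted p = 0.317, fry 0.0862, both downward). Markers of cell types other than B cells served as a check on the makeup of the samples. None of the 5 tested genes of T and NK cells (camera adjusted p = 0.317), the 7 of monocytes and macrophages (camera adjusted p = 0.837; median -0.02, or 0.03 with the GC offset and 0.04 to 0.43 when 1 library was left out, camera direction upward) or the 7 of stroma, endothelium and epithelium (camera adjusted p = 0.569) was called by edgeR, adjusted over all genes or over the list alone.

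In all, camera called 17 of the 37 lists, 11 higher and 6 lower, and fry called 22. Some called lists share members, so their calls are not independent of each other. BIRC3 is in the lists of NF-kB targets and apoptosis regulators, and IRF4 in those of NF-kB targets and plasma-cell genes. None of the 17 calls held with an estimated correlation. That setting tests on the 2 residual degrees of freedom, so a lost call decides little for a list whose estimated correlation is small. The replication list had an estimated correlation of -0.0085, below the preset 0.01, yet its camera p went from 1.2e-08 to 0.0213. Among the called lists, the estimated correlation was large for the ribosomal proteins (0.727) and the mitochondrial mRNAs (0.698). The preset value is far below these estimates, so the camera calls of these lists are in doubt. By fry neither passed (adjusted p = 0.0701 and 0.0907). Camera asks whether a list moved more than the other genes, while fry asks whether its members moved, on balance, one way. The vehicle libraries differed from each other more than the Spautin-1 libraries did, with a median absolute log2 difference per gene of 0.18 against 0.10. Over 9131 protein-coding genes, the difference between the vehicle libraries rose with the GC content of the transcript (Spearman rho 0.452 across genes, which are not independent replicates), and that between the Spautin-1 libraries had a rho of 0.0474. From the lowest to the highest decile of GC content, the share of genes called higher went from 19.6 to 7.67% and the share called lower from 8.53 to 20%.

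**Figure D5:**
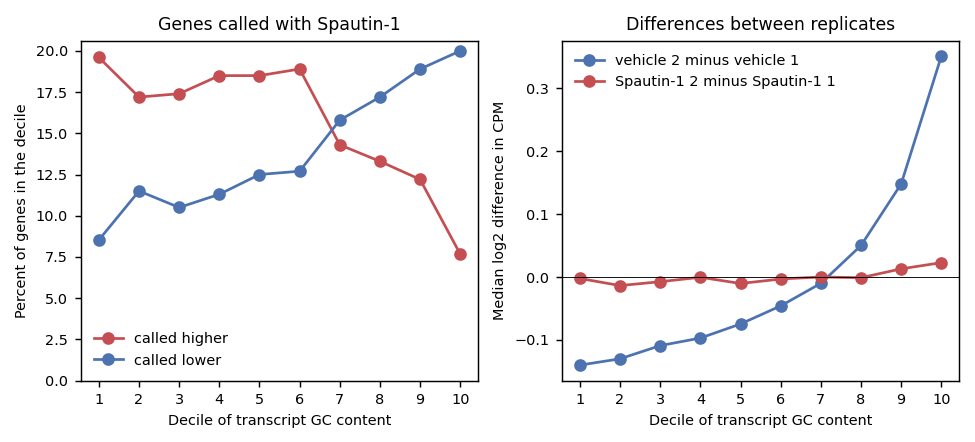
Left, percent of protein-coding genes called higher (red) and lower (blue) with Spautin-1 in each decile of transcript GC content; right, median log2 difference in CPM between the libraries of one group by decile (blue vehicle, red Spautin-1). The vehicle difference goes from -0.14 in the lowest to 0.35 in the highest decile.

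Some counts cannot be assigned to 1 gene alone. ZNF587B, SAT1, PCBP2, CLN3, DDIT3, FEN1, CCND2, GRWD1, HLA-DMB, FOXP1, H2AC6, MT1X and USP13 share exonic bases with another tested gene on the same strand. Among the genes that overlap a tested gene on the opposite strand are NPC1, SREBF1, HSP90AA1, NOP16, NBR1, NQO1, BIRC3, BCL2L1, PLK1, MYC, IL2RA, BCL6, UVRAG, NUP153, ALDOC, UQCRB, COX6C, NDUFS7 and IER2. The genes named above beyond the fixed rule were chosen after their values were seen: GCH1, GSS, ALOX12, NFS1, PSPH, BAG3, PSMA7, UCHL3, OTUD6B, ATG101, ATG7, SQSTM1, SGSH, NPM1, TNFAIP2, MT1F, MT1G, MT2A, SLC30A1, SPIB, POU2F2, SYK, HLA-B, NDUFS4, COX7C, PFKP, SLC2A1 and SLC16A3.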

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

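The tests without mitochondrial genes, with both the GC offset and vehicle replicate 2 left out, and with offsets in the list tests were chosen after the data were seen. With an adjusted p under 0.01, 1077 genes were higher and 861 lower; at least 2-fold, 764 and 559; and by glmTreat against a 1.5-fold change, 460 and 225. Leaving out 1 library gave 1067 to 2981 genes higher and 780 to 2785 lower, and 13 to 16 lists called; the lone library left in a group was assumed to vary like the other group. Of the 4045 called genes, 43.2% kept their call and direction without Spautin-1 replicate 2, 56.5% without Spautin-1 replicate 1, 84.9% with DESeq2 and 96.7% with the GC offset. No called gene changed sign in any of the settings that refit all genes. In all 4045 called genes both Spautin-1 libraries lay beyond both vehicle libraries, so leaving out a library could hardly reverse a sign. Across the named genes, of which 92 of 100 were called, 7 of 1994 values changed sign, each in a gene that was not called. With the replicate block 2615 genes were higher and 2485 lower, and 16 lists were called. The share of called genes that were higher lay between 46.0 and 57.8%.

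With an estimated correlation 0 of the 37 lists were called, against 17 with the preset one, 22 by fry and 21 by cameraPR. The estimated setting has little power with 2 residual degrees of freedom. In simulated data with each gene drawn independently, the ribosomal protein list, when shifted, reached p = 0.00688 by camera with an estimated correlation, before adjustment. The real list had an estimated correlation of 0.727, so the simulation does not show how this setting behaves on correlated lists. At this depth and replication, 19.4% of 1.5-fold changes were recovered in simulated data with 200 of 18368 genes changed; more genes passed in the real data, which loosens the threshold, so this share does not carry over to them. Without 1 Spautin-1 library the spread came from the vehicle libraries alone, which differed more from each other (median absolute log2 difference 0.18 against 0.10). No called gene changed sign in these fits, which the separation of the groups in every called gene had largely fixed in advance. Fewer calls there need not mean smaller changes, and other reasons were not tested.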

Other observations

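The family search, the immunoglobulin and tRNA values, the Cochran test and the histone comparison for the mitochondrial transcripts, and the GC offset test for the ribosomal protein list were chosen after the results they concern were seen; the other tests weighed here had their outcomes set out beforehand. Immunoglobulin constant-region genes, which encode the constant parts of antibodies, had a median log2 fold change of -0.86, and 10 of 12 tested were lower and 0 higher by edgeR. Several of these genes resemble each other closely, and how multi-mapped reads were handled is not given, so their counts are uncertain and not independent. IGHG3 fell from 819 and 1035 CPM in the vehicle libraries to 517 and 511 CPM in the Spautin-1 libraries, and IGHG1 from 316 and 469.8 to 179 and 178 CPM. Summed over constant genes, the ratio of Spautin-1 to vehicle was 0.542 for the heavy-chain locus, 0.789 for the kappa locus and 0.554 for the lambda locus, and 10 genes were also lower with the GC offset.

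Among families of genes sharing a symbol stem, 252 with at least 8 tested members were compared by camera and 5 were called. The helicase-related DHX family was lower by camera (8 of 16 called, adjusted p = 0.0321, p = 0.148 with an estimated correlation). So were the ribosomal RNA processing family RRP (6 of 9, adjusted p = 0.0321, estimated-correlation p = 0.19) and the stem MCM (8 of 10, adjusted p = 0.0321, estimated-correlation p = 0.128). The MCM stem covers replication helicase genes and others, such as MCM3AP. Several RRP and MCM genes are also in the biogenesis and replication lists, so these calls partly repeat those of the lists. The lipid transporter family ABCA was higher (5 of 8; adjusted p = 0.0234; p = 0.139 with an estimated correlation), as was WASH (5 of 8; adjusted p = 0.0234; p = 0.0728), whose tested members are near-identical copies with uncertain counts.

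Genes of high GC content were called higher less often and lower more often, from 19.6 and 8.53% in the lowest decile to 7.67 and 20% in the highest. Without vehicle replicate 2 the Spearman rho of log2 fold change with GC content was -0.0126, against -0.168 with all libraries and -0.277 without vehicle replicate 1, so a GC trend of vehicle replicate 2 is a candidate explanation for this gradient. It cannot account for the called genes as a whole, since 96.7% stayed called in the same direction with the GC offset. No biological explanation of the gradient was tested.

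Mitochondrial transcripts changed unequally, with mRNAs and rRNAs between 1.31 for MT-RNR2 and -0.29 for MT-ND1 on the log2 scale, and of the 22 tRNAs 8 were lower and 2 higher; the unknown strand setting limits MT-ND6 and the light-strand tRNAs. A larger mitochondrial share alone would raise the transcripts alike, but over all 14 heavy-strand mRNAs and rRNAs Cochran Q per degree of freedom was 28.5 (about 1 where members change alike, taking each SE as known), so a larger share could be part of the pattern but not the whole of it. With the GC offset 98.6% of the difference between MT-RNR2 and MT-ND1 of 1.60 (SE 0.115) stayed. Over protein-coding genes the median log2 fold change went only from 0.098 in the lowest to -0.178 in the highest GC decile. A trend of that size is too small for this difference, so the offset test could not have come out otherwise. Less complete poly(A) selection and a change in the cells cannot be told apart: histone mRNAs, which lack a poly(A) tail, had a median of -0.67 (10000 random lists, -0.49 to 0.41 without their outer tails), but they follow DNA replication genes, which were also lower. The compound's effect on mitochondrial transcripts stays open as well.

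Of 53 ribosomal protein mRNAs 33 were higher, at a list median of 0.42 on the log2 scale, and of 34 ribosome biogenesis mRNAs 15 were lower, at -0.29 (15 and 6 without Spautin-1 replicate 2). Camera called both lists, but neither with an estimated correlation (adjusted p = 0.539 and 0.381), and fry did not call the first (0.0701). The first median was 0.414 with the length offset and 0.404 with the GC offset, and the second was -0.31 and -0.26. Over protein-coding genes the log2 fold change followed length (Spearman rho 0.0535) and GC content (-0.168) only weakly. A large shift with either offset was therefore unlikely from the start. The length was the exonic length of each gene, so a trend with the length of the mRNAs themselves was not tested. The smallest of the 4 differences in the ribosomal protein median between a Spautin-1 and a vehicle library was 0.30. The difference was 0.13 between the vehicle and 0.11 between the Spautin-1 libraries. These within-group values each rest on 1 pair whose spread may be technical, so variation between cultures cannot be judged from them. Reads shared with ribosomal protein pseudogenes were not tested and stay open, beside a response of the cells to the compound, which may be involved.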
